A study of Mus musculus with 6 samples.

How the data were processed

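Gene expression was measured in mouse lymph node T cells on 6 single-colour Affymetrix whole-genome mouse arrays, a design that reads each transcript with 1 or more probe sets. Per the labels, 3 arrays hold T cells of Ezh2 fl/fl mice and 3 hold Ezh2 deficient T cells. The labels give no batch, sex, age or pairing and do not say whether the samples came from separate animals, so the p-values measure only the spread between these samples, which may be partly technical. The sample titles number the arrays in a single run across both groups, which pairs none of them. In the text the replicates are numbered within each group in that order.

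The deposited values are intensities on a linear scale, 1 per probe set and array, for 45101 probe sets. The software and settings that the authors used to make these intensities are not given in the sources used here. In the deposited table the trimmed mean intensity, leaving out 2% of the values at each end, was 500.002 on every array, as after scaling to a common target. No detection calls were used here. The median intensity differed by 15.2% between the arrays, above the 10% tolerance that was fixed before the data were examined, so the arrays were quantile normalised for the main analysis and the deposited scaling was kept as an alternative. The intensities were then turned into log2(intensity + 43.3), where 43.3 is the 20th percentile of all positive values. Fold changes are on this scale and understate the change of dim probe sets. The 64 control probe sets were left out of the tests, as were probe sets whose mean log2 value lay below the 40th percentile, which left 27022 probe sets.

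Differences were tested with limma (version 3.58.1, in R 4.3.3) by a linear model for each probe set followed by eBayes with an intensity trend, as Ezh2 deficient minus Ezh2 fl/fl over all 6 arrays, with 4 residual degrees of freedom per probe set and no covariate. P-values were adjusted by the Benjamini-Hochberg method over the 27022 probe sets, and a probe set was called at an adjusted p under 0.05. All tests were two-sided. The Ezh2 probe set was tested by itself as the targeted gene, so its unadjusted p decides, and an exact permutation test of its 6 values was added, for which 3 arrays against 3 allow no p below 0.10. The number of arrays limits the precision. On simulated log2 values with the spread of these arrays and 27022 probe sets, only the limma step was run. It recovered 24% of 50 probe sets changed 1.5-fold, 74% of 50 changed 2-fold, 98% of 50 changed 4-fold and 100% of 50 changed 5-fold. There were 8 false calls among 156. The noise was independent between probe sets, and the normalisation and filter were not rerun. With 156 calls the adjustment is also more lenient than with the 1 call found in the real data. These shares therefore overstate what the real comparison could recover.

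Gene names came from the platform annotation supplied with the table. Of the probe sets other than controls, 34945 had 1 gene symbol, 932 had several and 9160 had none, and a probe set was named only where it had 1. A RefSeq gene table of the GRCm38.p6 assembly matched 34741 of the named probe sets by gene identifier, changed 0 symbols, and was otherwise used only to find neighbouring genes. Affymetrix names ending in _s_at or _x_at mark probe sets that can match several transcripts.

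A total of 30 gene lists were fixed before the data were examined, of which 29 had the required 5 or more tested members. Each of the 12275 tested genes entered with its brightest probe set. Lists were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry beside it, and Benjamini-Hochberg adjustment over the 29 lists. Camera compares the genes of a list with all other genes, and fry asks whether they move, on balance, in the same direction. For single genes of a list, p-values were also adjusted over the list alone. The rule for the genes named in the text was fixed beforehand. It took the Ezh2 probe sets, then up to 12 called genes per direction whose groups did not overlap, filled up to 8 per direction with the genes of smallest unadjusted p, and for each list up to 4 called genes or otherwise the 2 with the smallest unadjusted p. Genes named outside this rule were chosen after their values were seen, and the text says so.

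The alternatives fixed beforehand were the deposited scaling, its median centring, a pseudocount 4 times lower and 4 times higher, no filter, a filter at the 60th percentile, eBayes without trend, robust eBayes (with statmod 1.5.0), array weights, each array left out in turn, other thresholds, genes in place of probe sets, and the other list tests. Counts of genes called over a list alone under these alternatives were added after the data were seen. Group values are means ± SD of normalised intensities over 3 arrays unless the text says otherwise.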

Results

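Ezh2 is the catalytic subunit of Polycomb repressive complex 2, which methylates lysine 27 of histone H3 at silenced genes. The series compared lymph node T cells of Ezh2 fl/fl mice, whose Ezh2 alleles carry loxP sites in the usual notation, with Ezh2 deficient lymph node T cells, on 3 arrays each. Median deposited intensities ran from 163.3 to 188.1, with the highest value on Ezh2 fl/fl replicate 1. Between arrays of the same group the Pearson correlation of log2 values across probe sets was 0.972 to 0.982, and between groups it was 0.969 to 0.980. Ezh2 fl/fl replicate 1 lay apart from the other 5 arrays on the first principal component, which held 30.6% of the variance, at a coordinate of -41.5 where the others ran from 1.48 to 15.1.

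Ezh2 mRNA fell in the deficient T cells. The single Ezh2 probe set averaged 688 ± 111 in the Ezh2 fl/fl arrays and 282 ± 6.55 in the deficient arrays (SD, n = 3 each), which left 41.0% of the control level. The log2 difference was -1.16 (SE 0.13), with a limma p of 7.83e-06 for this pre-specified probe set and an adjusted p of 0.0705 over all probe sets. Every deficient array lay below every control array, which gives the smallest exact permutation p this design allows, 0.10. The labels do not say which part of the gene is deleted, so the probe set may lie outside it and its signal does not measure how many cells lost the gene.

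The transcript that changed most clearly, ahead of Ezh2 itself, was Fam241a, a gene of poorly known function, which fell 5.31-fold. Its probe set averaged 1128 ± 245 in the controls and 174 ± 1.24 in the deficient T cells, a log2 difference of -2.41 (SE 0.15, adjusted p = 0.00106). Its other probe set had a log2 difference of -1.22 (adjusted p = 0.218), with the groups not overlapping on either probe set. Fam241a was the 1 probe set of 27022 that limma called, with 0 called higher. At an unadjusted p under 0.05 there were 1038 probe sets higher and 913 lower, against 1351.1 expected by chance in all. The groups did not overlap for 3538 probe sets (13.1%), where chance gives 10% on average. Probe sets can vary together, so a single grouping may stray from both of these averages. Neither excess was tested against other groupings of the arrays. The number of called probe sets was 3 without Ezh2 fl/fl replicate 1 and 6 without Ezh2 deficient replicate 2, and Fam241a was among them each time.

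Below the threshold, the genes with the smallest p on the higher side included Myb, a transcription factor of early lymphocyte development. Myb averaged 764 ± 118 in the controls and 1699 ± 272 in the deficient T cells (log2 difference 1.11, adjusted p = 0.0972), and its other probe sets were at 0.95 and 0.64. A probe set of Prim2, a subunit of DNA primase, was near the floor in the controls at 50.7 ± 8.44 against 232 ± 39.8 in the deficient arrays (adjusted p = 0.0972), so its fold change is not given. The other Prim2 probe sets, both brighter, were at 0.18 and -0.03. Itm2a, which encodes a membrane protein of T cells, averaged 3292 ± 631 in the controls and 5444 ± 83.0 in the deficient arrays (log2 difference 0.74, adjusted p = 0.209). Rabgap1l was at 0.53, with its other probe sets from 0.04 to 0.47, and Serf1, dim in the controls at 90.9 ± 23.5, was at 1.11, with others at 0.72 and 0.27. The remaining genes on this side were the interferon-induced Oas1a at 1.22, Ddx60 at 0.73 and Ifi44l at 1.67. None of these passed over all probe sets, and their adjusted p ran up to 0.264 for Ifi44l.

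On the lower side, Lgals1, which encodes galectin-1, averaged 4846 ± 690 in the controls and 2889 ± 291 in the deficient T cells (log2 difference -0.73, adjusted p = 0.166), with its other probe set at -0.82. Capg, an actin filament capping protein, was at -0.88 (adjusted p = 0.248) and at -0.45 on its other probe set. The semaphorin gene Sema4a was at -0.34 and the phosphatase gene Ppm1m at -0.53, and E130119H09Rik averaged 221 ± 48.2 in the controls and 66.4 ± 5.28, near the floor, in the deficient arrays. Tmem176a was at -1.25 on the probe set with the smallest p but at -0.23 and -0.07 on its others. BC004004 was at -0.94, with 3 of its 5 probe sets lower and 2 higher.

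**Figure D1:**
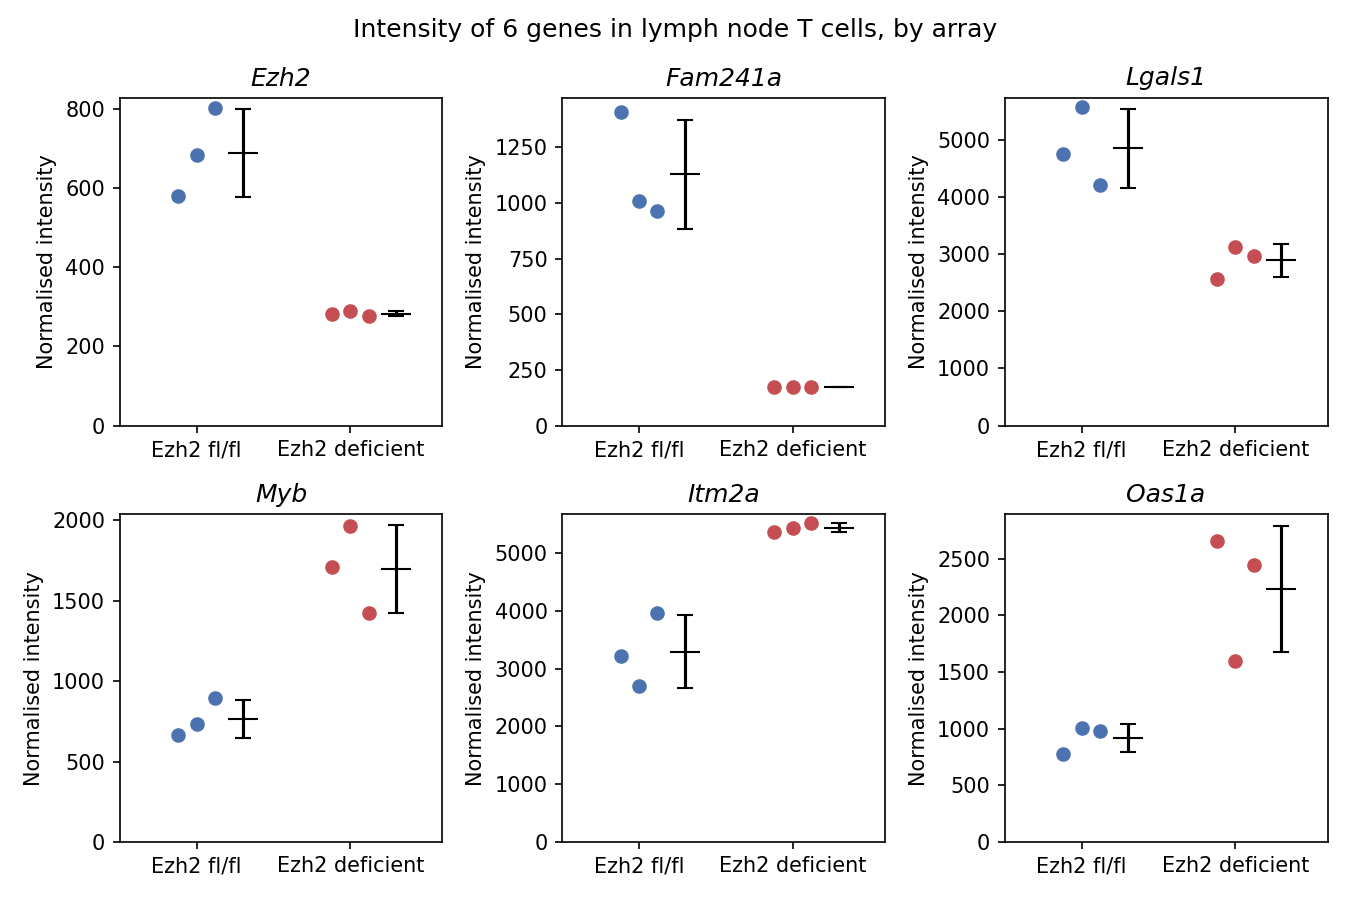
Normalised intensity (vertical axis, linear scale from 0, arbitrary units) of 6 genes in the 3 Ezh2 fl/fl arrays (blue points) and the 3 Ezh2 deficient arrays (red points), 1 probe set per gene, with the mean and SD of each group in black. The groups do not overlap for any of the 6 genes, and Fam241a lies between 173 and 176 in the deficient arrays against at least 965 in the controls.

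Interferon response genes stood higher in the deficient T cells as a group. Of 55 tested members, 48 had a positive difference, and 25 rose when adjusted over the list alone, while 0 fell and 0 passed over all probe sets. Oas1a, an antiviral oligoadenylate synthetase, averaged 920 ± 122 in the controls and 2234 ± 560 in the deficient arrays (log2 difference 1.22, adjusted p = 0.00381 over the list alone). The antiviral GTPase Mx1 averaged 470 ± 202 and 1268 ± 309 (log2 difference 1.40, adjusted p = 0.0143 over the list alone). The median difference of the list was 0.34, and camera called the list higher (adjusted p = 2.88e-21). The list did not pass with an estimated correlation (adjusted p = 0.451 with an estimated correlation) or by fry (adjusted p = 0.385).

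The interferon genes did not move evenly across arrays. The median of the list, relative to the mean of the controls, was -0.11, -0.01 and 0.10 in Ezh2 fl/fl replicates 1, 2 and 3, and 0.50, 0.08 and 0.43 in Ezh2 deficient replicates 1, 2 and 3, so that deficient replicate 2 lay within the range of the controls. The count of 25 interferon genes became 4 without Ezh2 fl/fl replicate 1, 1 without Ezh2 fl/fl replicate 2, 1 without Ezh2 deficient replicate 1 and 1 without Ezh2 deficient replicate 3, but 38 without Ezh2 deficient replicate 2. It was also 3 by eBayes without trend, 7 by robust eBayes, 15 with array weights and 15 without the filter. Oas1a kept its call over the list alone with each of the 6 arrays left out.

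Camera also called the marker lists of dendritic cells and of natural killer cells higher in the deficient arrays. Of 16 tested dendritic cell markers, 13 were higher, with a median of 0.14 (camera adjusted p = 0.0172, adjusted p = 0.451 with an estimated correlation). The chemokine Ccl22 was at 0.51, dim at 110 ± 10.5 in the controls and 175 ± 17.6 in the deficient arrays. The actin bundling protein Fscn1 was at 1.18 with overlapping groups (0.20 on its other probe set). Over the list alone 0 members passed, with 2 at an unadjusted p under 0.05. Of 15 natural killer cell markers, 11 were higher, with a median of 0.11 (camera adjusted p = 0.0400, adjusted p = 0.451 with an estimated correlation). The smallest p belonged to the chemokine Xcl1 at 0.68 and the protease Gzma at 0.63, both dim. Xcl1 averaged 126 ± 26.4 in the controls and 226 ± 34.7 in the deficient arrays, and Gzma 185 ± 46.3 and 306 ± 44.2. Without Ezh2 fl/fl replicate 3 only 7 of the 15 were higher, and the median turned to -0.018. The brightest members, picked after their values were seen, are also expressed by T cells, with Ccr7 at 6065 ± 464 in the controls and 6556 ± 277 in the deficient arrays and Nkg7 at 6970 ± 465 and 6553 ± 269. Of the natural killer markers, 14 stand on another list too, and of the dendritic cell markers 5, with 1 of these on the interferon list. The Th1 list also stood higher, with 11 of 16 members positive and a median of 0.16 (camera adjusted p = 0.0374, adjusted p = 0.501 with an estimated correlation). In it the interferon gamma receptor subunit Ifngr1 was at 0.21 and the cytokine Tnf at -0.35. Of the 16 Th1 members, 10 stand on another list too, with 1 of these on the interferon list. The dendritic cell call was lost without the filter and without Ezh2 deficient replicate 1. The natural killer call was lost without the filter, with the filter at the 60th percentile, by eBayes without trend, with the mean of all probe sets of a gene, and without Ezh2 deficient replicate 1 or 2 or Ezh2 fl/fl replicate 3. The Th1 call was lost without the filter, by eBayes without trend, with array weights, with the mean of all probe sets of a gene, and without Ezh2 fl/fl replicate 1 or Ezh2 deficient replicate 1. All 3 calls were lost by fry as well.

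**Figure D2:**
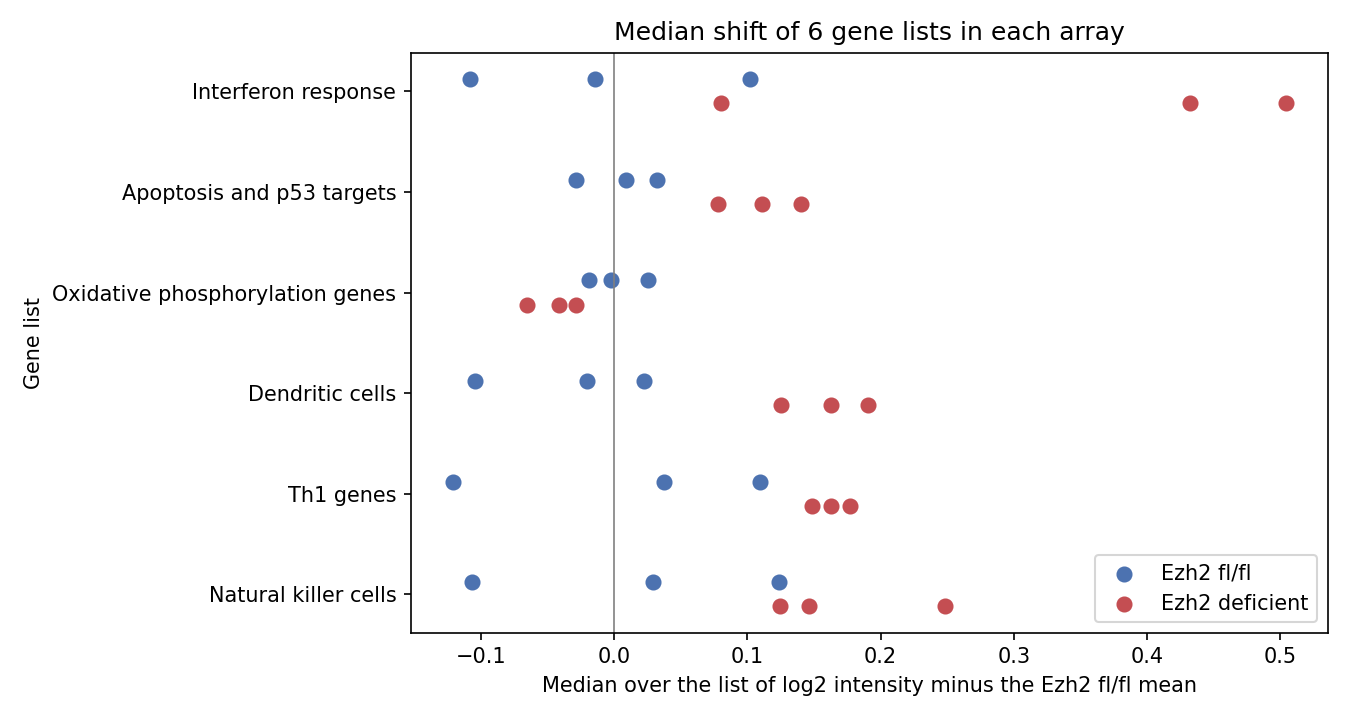
Median over the genes of a list of the log2 intensity minus the mean of the Ezh2 fl/fl arrays (horizontal axis, log2 units), for the 6 lists that camera called (vertical axis), with 1 blue point per Ezh2 fl/fl array and 1 red point per Ezh2 deficient array. For the interferon list deficient replicate 2, at 0.08, lies below Ezh2 fl/fl replicate 3, at 0.10. The oxidative phosphorylation list, lower here, turns to a median of 0.023 under median centring of the deposited scaling, and the natural killer list, higher here, to -0.018 without Ezh2 fl/fl replicate 3.

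Genes of effector and memory T cells did not move together. Of 59 tested members, 35 were higher and 24 lower, with a median of 0.03 (camera adjusted p = 0.542). Without Ezh2 fl/fl replicate 3 only 28 were higher, and camera called the list higher without Ezh2 fl/fl replicate 2 (adjusted p = 0.0493). Within the list 4 genes fell when adjusted over the list alone: Lgals1 (adjusted p = 0.00499), the calcium-binding protein gene S100a6 (log2 difference -0.79, adjusted p = 0.0211) and, named after their values were seen, S100a4 (-0.83, adjusted p = 0.0211) and Crip1 (-0.28, adjusted p = 0.0211). S100a6 averaged 683 ± 80.5 in the controls and 382 ± 96.5 in the deficient T cells. Lgals1 kept its call over the list alone with each of the 6 arrays left out, while the count of 4 became 1 without Ezh2 fl/fl replicate 1 or Ezh2 deficient replicate 1, and 15 (8 higher and 7 lower) without Ezh2 fl/fl replicate 2. By eBayes without trend it was 0. Of genes picked after their values were seen, Ifng was at 0.38, Tbx21 at 0.40 and Cxcr3 at 0.48, whereas Cxcr6 was at -0.52, Tnf at -0.35, Ccr6 at -0.33, Klrk1 at -0.33 and Klrg1 at -0.31, with 0 of these passing over the list alone.

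Early activation genes included 3 that rose and 1 that fell when adjusted over the list alone, among 36 tested. Cd69, a receptor that appears soon after activation, averaged 7010 ± 297 in the controls and 9188 ± 735 in the deficient T cells (log2 difference 0.39, adjusted p = 0.00980 over the list alone). Tnfaip3, an inhibitor of NF-kappaB signalling, was at 0.54 (adjusted p = 0.0119 over the list alone). The other members with such a call, named after their values were seen, were the inhibitory receptor gene Ctla4 at 0.40 and Tnfrsf18 at -0.27 (each adjusted p = 0.0370 over the list alone). The list itself missed the camera threshold (adjusted p = 0.0574). It was called higher with the filter at the 60th percentile (adjusted p = 0.0401), without Ezh2 fl/fl replicate 2 (adjusted p = 0.0493) and without Ezh2 deficient replicate 3 (adjusted p = 0.00284). Its count of 4 was 0 without Ezh2 deficient replicate 2 and by eBayes without trend, 2 without Ezh2 fl/fl replicate 2, and 6 with array weights or the filter at the 60th percentile.

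Naive and quiescent T cell genes did not pass as a list (26 of 42 higher, camera adjusted p = 0.0587), though camera called the list higher without Ezh2 fl/fl replicate 1 or 3 or Ezh2 deficient replicate 3. Itm2a rose when adjusted over the list alone (adjusted p = 0.00552) and did so with each of the 6 arrays left out but not by eBayes without trend, while the cytokine gene Lta was at -0.35 (adjusted p = 0.167 over the list alone). Among 54 T cell receptor signalling genes, 30 were higher (camera adjusted p = 0.542), and 24 without Ezh2 fl/fl replicate 1. Cblb, a ubiquitin ligase that restrains receptor signalling, rose when adjusted over the list alone (log2 difference 0.39, adjusted p = 0.0233), in 2 of the 6 runs that left out an array, and the kinase gene Tec was at 0.47. Among 74 actin cytoskeleton regulators, 50 were lower and 24 higher (camera adjusted p = 0.284). This majority turned with the scaling, to 42 higher under the deposited scaling and 52 under its median centring, and camera called the list lower without Ezh2 fl/fl replicate 1 (adjusted p = 0.0308). Capg fell when adjusted over the list alone (adjusted p = 0.0136), in 3 of the 6 runs that left out an array, and Arpc4 was at -0.24. By eBayes without trend the calls of Cblb and Capg over the list alone were lost.

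Regulatory T cell genes went in both directions. Of 24 tested members, 3 rose and 6 fell when adjusted over the list alone, and the list had no common direction (median -0.10, camera adjusted p = 0.468). The integrin gene Itgae averaged 2709 ± 674 in the controls and 1568 ± 207 in the deficient T cells. Its log2 difference was -0.75 (adjusted p = 0.0197 over the list alone), and -0.41 with overlapping groups on its other probe set. The zinc finger gene Plagl1 was at 0.75 (adjusted p = 0.0197 over the list alone) but at -0.24 on its other, similarly bright probe set. Foxp3, the defining transcription factor of these cells, was picked after its value was seen and was at -0.28 (adjusted p = 0.1504 over the list alone). The count of 9 was 0 without Ezh2 deficient replicate 1, 2 without Ezh2 deficient replicate 2, 5 without Ezh2 deficient replicate 3, and 6 without Ezh2 fl/fl replicate 1 or 2.

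The markers of CD4 and CD8 T cells did not pass as lists. Cd4 was at -0.04 and Cd8a at -0.06, both picked after their values were seen. Among 14 CD8 markers, 3 fell when adjusted over the list alone: Cd7 (log2 difference -0.56, adjusted p = 0.0101), Itgae (adjusted p = 0.0116) and, named after its value was seen, Cd8b1 (-0.17, adjusted p = 0.0337). Among 11 CD4 markers, Izumo1r rose (0.57, adjusted p = 0.0301) and Tnfrsf4 fell (-0.27, adjusted p = 0.0383) when adjusted over the list alone, the latter in 0 of the 6 runs that left out an array. The 3 CD8 calls became 0 without Ezh2 deficient replicate 1, 1 without Ezh2 fl/fl replicate 3 and 5 without Ezh2 fl/fl replicate 1 or 2, and the 2 CD4 calls became 0 without Ezh2 fl/fl replicate 3 or Ezh2 deficient replicate 1 or 2 and 1 with any other array left out. By eBayes without trend the counts were 2 for CD8 and 0 for CD4. Camera gave adjusted p = 0.921 for the CD8 list and 0.982 for the CD4 list. Each list had a median just below 0 and a mean just above it.

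Among 40 chemokine receptor, integrin and homing genes, 20 were higher and 20 lower (camera adjusted p = 0.982), and the median lay just below 0 and the mean just above it. Rgs1, which dampens chemokine receptor signalling, rose when adjusted over the list alone (log2 difference 0.58, adjusted p = 0.0307), as did Cxcr5 at 0.53 (adjusted p = 0.0307), while Itgae fell (adjusted p = 0.0307). These 3 calls became 0 with any Ezh2 deficient array left out, 5 without Ezh2 fl/fl replicate 1, 7 without Ezh2 fl/fl replicate 2, 2 without Ezh2 fl/fl replicate 3 and 0 by eBayes without trend. Of 14 Th2 genes, 9 were higher (camera adjusted p = 0.176, called higher without Ezh2 deficient replicate 3), with the transcription factor genes Gfi1 at 0.40 and Maf at 0.39.

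**Figure D3:**
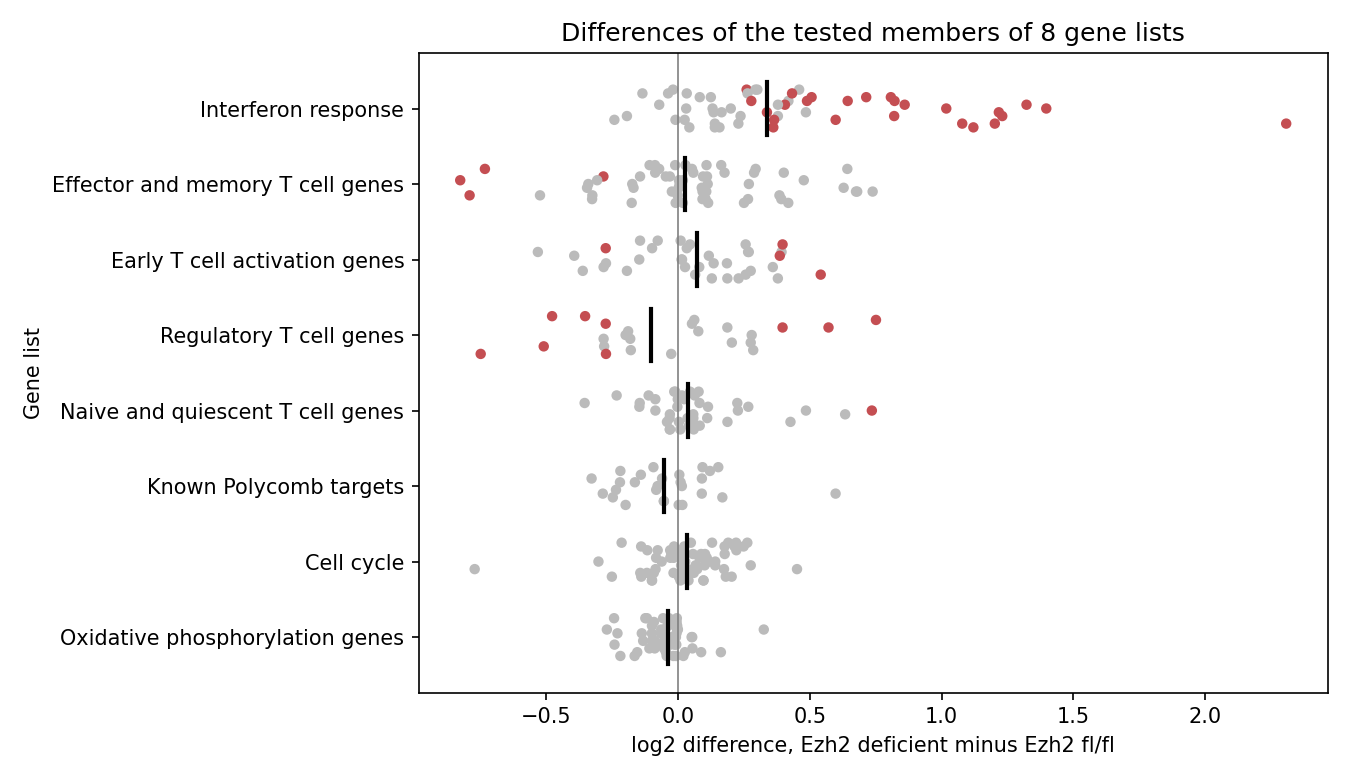
Log2 difference, Ezh2 deficient minus Ezh2 fl/fl (horizontal axis), of the tested genes of 8 lists (vertical axis), 1 point per gene spread vertically for legibility, with red for an adjusted p under 0.05 over the list alone, grey for the others, and a black bar at the median of the list. The interferon genes have a median of 0.34, whereas the regulatory T cell list has 3 red points above 0 and 6 below. The oxidative phosphorylation median of -0.04 turns to 0.023 under median centring of the deposited scaling.

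Of 31 tested Polycomb and H3K27 demethylase genes, Ezh2 alone fell when adjusted over the list alone (adjusted p = 0.000243), and Phc1 was at 0.44 (adjusted p = 0.110 over the list alone). The count of 1 was 2, both lower, without Ezh2 fl/fl replicate 1 and with array weights. Of genes picked after their values were seen, Bmi1 was at -0.43 and Kdm6b at -0.29 (each adjusted p = 0.128 over the list alone), the Ezh2 partners Eed and Suz12 at -0.04 and 0.06 and the related Ezh1 at -0.03. Known developmental Polycomb target genes did not pass as a list. Of 27 tested by limma, 12 were higher and 15 lower, 0 had an unadjusted p under 0.05, and camera gave an adjusted p of 0.676. Igf2, dim in the controls at 118 ± 67.3, was at 0.60 and Msx1 at -0.25 (0.08 on its other probe set). Only 7 of the 27 were higher under the deposited scaling or its median centring, and 7 of 29 without Ezh2 deficient replicate 1. Without the intensity filter 94 were tested, 47 higher and 47 lower, with 2 higher and 2 lower at an unadjusted p under 0.05 and 0 called over the list alone.

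Apoptosis and p53 target genes stood higher as a list, with 30 of 40 positive and a median of 0.10 (camera adjusted p = 0.000288, adjusted p = 0.213 with an estimated correlation). Bbc3, a proapoptotic Bcl-2 family gene, averaged 571 ± 102 in the controls and 958 ± 112 in the deficient T cells and rose when adjusted over the list alone (log2 difference 0.71, adjusted p = 0.0248), in 2 of the 6 runs that left out an array. Casp9, dim in the controls at 123 ± 30.4, was at 0.69 (adjusted p = 0.0628 over the list alone) but at 0.014 on its other probe set. The camera call of this list held with each of the 6 arrays left out. Oxidative phosphorylation genes stood slightly lower, with 51 of 59 negative and a median of -0.04 (camera adjusted p = 0.0108, adjusted p = 0.451 with an estimated correlation), including Ndufa10 at -0.24 (0.28 on a dim second probe set) and Ndufb2 at -0.27. This call was lost under the deposited scaling, with 29 of 59 higher, and under its median centring, with 37 of 59 higher and a median of 0.023, by eBayes without trend, and without Ezh2 deficient replicate 1 or Ezh2 fl/fl replicate 3.

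Cell cycle genes did not pass as a list, with 41 of 64 higher, a median of 0.04 (camera adjusted p = 0.195), Mcm2 at -0.77 but at 0.05 on its other probe set, and Plk1 at 0.45. The majority rested on Ezh2 deficient replicate 2, where the list median was 0.18 above the controls against -0.02 in each of the other deficient arrays. Without that array 24 of 62 were higher, and without Ezh2 deficient replicate 3 camera called the list higher (adjusted p = 0.0369). Immediate early and heat shock genes had 21 of 33 members higher (camera adjusted p = 0.0574, called higher with the filter at the 60th percentile and without Ezh2 deficient replicate 2 or 3), with Ier5 at -0.16 and Egr2 at 0.26. Ribosomal protein genes had 20 of 42 members higher (camera adjusted p = 0.681), but 37 under the deposited scaling and 38 under its median centring, with Rpl12 at -0.23 and Rpl10a at -0.10, the latter at 0.02 under median centring of the deposited scaling. Camera called the ribosomal list higher under the deposited scaling (adjusted p = 0.000207) and under its median centring (adjusted p = 0.00107). The lists of T cell receptor signalling, naive T cell and immediate early genes were likewise called higher under both, with adjusted p = 0.0142, 0.000207 and 0.00198 under the deposited scaling.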

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

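The spiked-in Cre control probe sets, which detect an added bacteriophage transcript and were not tested, were brighter in all 3 Ezh2 deficient arrays than in any Ezh2 fl/fl array in the deposited intensities, by a mean log2 difference of 0.27 over 4 probe sets (exact permutation p = 0.10, the smallest this design allows). A further 14 probe sets, those of the spiked-in bacterial bio genes, differed by 0.26 with overlapping groups (exact permutation p = 0.2). The Cre signal relative to them differed by 0.01.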

How the results depend on the processing

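Ezh2 was lower with an unadjusted p under 0.05 in every alternative, from -1.28 to -0.91, and Fam241a was called in each alternative fit of probe sets. The count of called probe sets, 1 in the main analysis, was 6 at an adjusted p under 0.10, 3 with array weights, the deposited scaling or robust eBayes, and 2 with genes in place of probe sets or median centring; the added calls with weights, deposited scaling and robust eBayes were Ezh2 and an unnamed probe set, 1441556_at. Calls upward, 0 in the main analysis, numbered 1 with array weights, deposited scaling, median centring or robust eBayes. Calls downward, 1 in the main analysis, numbered 2 with array weights, deposited scaling or robust eBayes. Leaving out 1 array gave 1 to 6 called probe sets, 0 to 4 upward and 1 to 2 downward, with the highest total without Ezh2 deficient replicate 2. The 6 called gene lists became 10 with the deposited scaling or median centring, 3 without the filter or by eBayes without trend, 0 with an estimated correlation or fry, and 2 (without Ezh2 deficient replicate 1) to 12 (without Ezh2 deficient replicate 3) with 1 array left out. The fry test for change in either direction called 11 lists. The oxidative phosphorylation median reversed to 0.023 under median centring (adjusted p = 0.919; 0.000926 to 0.919 over its alternatives). The natural killer median turned to -0.018 without Ezh2 fl/fl replicate 3 (adjusted p = 0.345). The cause was not tested, apart from the arrays and genes that an alternative leaves out. Of 981 values of named genes other than Ezh2 under alternatives, 980 kept their direction or stayed outside the threshold as before. Only Fam241a of these genes was called in the main analysis, so a count this high was nearly fixed in advance. The exception was Oas1a, which passed over all probe sets without Ezh2 deficient replicate 2 (limma adjusted p = 0.0258, with 0.0258 to 0.505 over its alternatives). Fold changes of dim probe sets are limited by the added 43.3.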

Other observations

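The markers of the remaining cell types did not pass as lists. Of 26 tested B cell markers, 14 were higher (camera adjusted p = 0.680), and when adjusted over the list alone Cxcr5 and Plac8 rose (log2 differences 0.53 and 0.61, each adjusted p = 0.0358) and Cd72, named after its value was seen, fell (-0.48, adjusted p = 0.0358); these 3 calls became 0 without Ezh2 fl/fl replicate 1 or any Ezh2 deficient replicate, without the filter and by eBayes without trend, and 1 without Ezh2 fl/fl replicate 3. Among 21 macrophage and monocyte markers, 8 were higher, or 12 under median centring of the deposited scaling (camera adjusted p = 0.921), with Csf1r at -0.42 but at 0.29 and 0.12 on its other probe sets, and Grn at 0.23 but at 0.05 and -0.11 on its others. Among 8 granulocyte markers Il1b fell when adjusted over the list alone (-0.62, adjusted p = 0.0202), in 2 of the 6 runs that left out an array and not without the filter, and the mast cell gene Cpa3 was at -0.34 (camera adjusted p = 0.333 for the list). Among 28 stromal and endothelial markers the collagen chaperone gene Serpinh1 fell when adjusted over the list alone (-0.83, adjusted p = 0.0264), in 1 of those 6 runs and not with either other filter setting, and Col6a1 was at 0.40 (camera adjusted p = 0.862). All 6 tested adipose tissue markers were lower, with Slc2a4 at -0.92 and Retn at -0.50 (camera adjusted p = 0.0574), and camera called this list lower under the deposited scaling (adjusted p = 0.0213), under its median centring, and without Ezh2 fl/fl replicate 1 or Ezh2 deficient replicate 3. The hemoglobin genes Hba-a1 and Hba-a2 were at -0.38 and 0.22 in the erythrocyte and platelet list (camera adjusted p = 0.383).

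Among 20 thymocyte markers, Myb rose when adjusted over the list alone (adjusted p = 0.000432) and did so with each of the 6 arrays left out, while Cd8b1 was at -0.17 and the list did not pass (11 higher, or 8 without Ezh2 fl/fl replicate 2, camera adjusted p = 0.560). The gamma delta T cell list had 5 of 8 members higher (camera adjusted p = 0.788), with Cd163l1 at -0.79 and Maf at 0.39, and its median of 0.10 and mean of -0.03 differed in sign. Y-linked transcripts were abundant in both groups, with Eif2s3y at 2756 ± 114 in the controls and 2810 ± 176 in the deficient arrays, and Kdm5d at 981 ± 111 and 919 ± 51.9. Xist, the noncoding RNA of the inactive X chromosome, had a dim probe set of the _s_at kind at 351 ± 5.55 in the controls and 242 ± 23.9 in the deficient arrays, with an adjusted p of 0.0147 over only 4 tested sex-linked genes, fewer than a list required. Its other probe sets lay near the floor, below the filter, and went in opposite directions, from 34.5 to 21.7 and from 37.6 to 53.9. Among the 6 probe sets with an adjusted p under 0.10 were 2 without a gene name, 1441556_at with a log2 difference of 1.03 (adjusted p = 0.0705) and 1454521_at with -0.78 (adjusted p = 0.0972). Of the 100 tested genes that neighbour Ezh2 in the reference annotation, 2 had an unadjusted p under 0.01, Parp12 at 0.83 and Ndufb2 at -0.27, against 1.99% of all tested genes with a location.

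All tests in the rest of this part were chosen after the results they bear on were seen. The bootstrap intervals given below resampled the genes of a list and not the arrays, so they hold no spread between samples. With 6 arrays there are 10 splits into groups of 3, too few for a share under 0.05. The real split called 1 probe set and the highest other split 2, and 3 of the 10 splits called as many as the real split. The real split called 6 lists and the highest other split 5, so 1 of 10 reached that number. The interferon list median moved by 0.34 in the real split and by 0.36 in the highest other, which parted Ezh2 fl/fl replicates 1 and 2 and Ezh2 deficient replicate 2 from the rest, and 2 of 10 moved it as far.

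The higher interferon genes may reflect variation between arrays that has nothing to do with Ezh2. The lowest median of a deficient array minus the highest of a control array was -0.022 on the log2 scale, so the groups overlapped, as such variation would give. This rests on the same array medians as given in the results above and is no separate support. More macrophages or granulocytes in the deficient samples was argued against only as a broad gain of these cells, by their own marker medians of -0.018 and -0.070. The interferon median exceeded the higher of these by 0.35 (95% bootstrap interval over genes 0.21 to 0.52). The interval against each of these lists lay above 0. This excess decides nothing, because the interferon list was taken up as the list with the highest median of those tested. Only 21 of 40 macrophage and monocyte markers and 8 of 28 granulocyte markers were tested, so a small gain of such cells may be missed. More B cells, dendritic cells or natural killer cells stays open, because the excess over the highest of those medians was 0.20 with an interval of -0.03 to 0.35, and 2 B cell markers rose while 1 fell over the list alone. An effect of Ezh2 loss on interferon genes within T cells stays open as well and was not separately tested. The labels do not say how Ezh2 was removed. For every difference given here, an effect of the means of deletion therefore cannot be told apart from one of Ezh2 loss.

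The fall of Fam241a is a candidate for follow-up. A fault of a single probe set was argued against by the other Fam241a probe set, at -1.22 (SE 0.20). Of the 20 tested genes nearest to Fam241a, 0 had an unadjusted limma p under 0.01, against 1.99% of all tested genes with a location. This argues only against a stretch of DNA that strongly changes the expression of several genes. A changed stretch need not do so, and stays open otherwise. A genetic difference confined to Fam241a, and a dependence of Fam241a on Ezh2, may also each account for the fall, and neither was tested.

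Lgals1, S100a4, S100a6 and Crip1, whose median difference was -0.76, could be lower because the deficient samples held fewer cells of a kind rich in them. Whether the share of effector and memory T cells was smaller could not be decided. The median of that whole list was 0.028 (95% bootstrap interval -0.0092 to 0.10), so the list did not fall as a whole. It lay 2.36 SDs of its members above the median of the 4 genes. These 4 were picked as the only members called over that same list alone, all lower, so their median was bound to lie below it. The median of the 4 genes is no fair level for other lists either, because these genes were picked as lower. For macrophages and monocytes, the 21 tested markers of 40 had a median of -0.018 (-0.14 to 0.05), so no fall of that list as a whole was seen. This argues only against a broad loss of these cells. Markers near the floor could not show a fall, so loss of a small share stays open. A smaller share of regulatory T cells stays open, because the median of that list, -0.10 (-0.27 to 0.19), stands over 3 members that rose and 6 that fell over the list alone. Lower expression within the same cells after loss of Ezh2 stays open as well.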
